A study of Mus musculus with 16 samples.

How the data were processed

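The series comprises 16 Illumina bead arrays of RNA labelled as dorsal skin, from 15-day-old mice of a mixed strain background (C57/BL6;129Ola), 7 assigned by their labels to K14-cre; Gab1fl mutants and 9 to controls. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy columns, amplified and labelled with biotin. The arrays lie on 2 slides of 8 positions, and both slides hold both groups.

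The deposited table of raw values holds a summarised probe intensity and a detection p-value for each array and probe, exported from GenomeStudio per the submitters' processing notes, with no version given. A further deposited table holds the authors' normalized intensity on a linear scale. Setting its columns against the raw columns showed that it equals the quantile-normalized raw signal, with a median relative difference of 0.00648% and a largest one of 3.22%, and its array medians lie between 203.6 and 203.9. The order of probes was unchanged in every array, and no 2 arrays held identical values. A genome build is not given in the sources used here, and no coordinates are reported.

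Values were processed in R 4.3.3 with limma 3.58.1. Background was corrected by neqc (normal-exponential model with negative controls inferred from the detection p-value, offset 16), followed by quantile normalization and log2. Probes with a detection p below 0.05 on at least 7 of the 16 arrays were kept, which left 14504 of 25697. Probe names came from the platform annotation, with 23978 probes having 1 gene symbol, 0 several and 1719 none, and symbols were updated through gene identifiers of the RefSeq table for GRCm38.p6. The tested probes covered 10013 genes. For statements per gene, the probe with the highest mean was used. Median raw signal per array lay between 175.9 and 223.5, and the number of arrays and sources limits the precision.

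Before any averaging, arrays were compared with one another. Within each labelled group, arrays with a correlation above 0.99 were joined, which gave 5 sources. This threshold was set after seeing the data. The order of sources along the slide positions repeated, and every source was present on both slides. Arrays of a source were averaged, and limma was fitted to 2 mutant and 3 control sources (lmFit, eBayes with an intensity trend, 3 residual and 2.53 prior degrees of freedom), with Benjamini-Hochberg adjustment at 0.05. This departs from the fit set before the data were examined, which took the 16 arrays as separate samples without a covariate. That fit is reported as an alternative.

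Gene lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation and with fry as alternatives, over lists with at least 3 measured genes and Benjamini-Hochberg adjustment over all 41. Counts of genes adjusted over a list alone take no account of the number of lists. Those counts describe a list and are no separate test of it. The lists, the processing alternatives and the rule for naming genes were set before the data were examined. The rule named Gab1, up to 8 genes with the largest difference in each direction past the threshold, and the 2 genes with the smallest p in each list that passed and in 7 lists fixed in advance, which gave 38 genes. Other members of lists were added as examples after their values were seen. For Gab1 an exact two-sided permutation test over the 5 sources was added. Errors are SD over sources, and SE are those of the limma fit.

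The fits were tested on simulated data that kept each probe's mean, its spread between sources and its spread between arrays, in 20 runs of 14504 probes with 200 changed. Averaging by source recovered the simulated differences with a slope of 1.00 and called 13.3% of 2-fold, 62.2% of 4-fold, 85.8% of 8-fold and 87.5% of 16-fold changes, with 4.95 false calls per run. With no group difference it called 0.05 probes per run, whereas the fit to 16 separate arrays called 2518 on average (2412 to 2674). The simulated probes varied independently of one another, without the correlation between genes in the real data. These rates therefore need not hold for the real arrays.

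Alternatives covered the background correction, the scaling, the authors' table, the filter on dim probes, the slide as a block and each slide by itself, the title numbers as a replicate block, the Y-linked level as a covariate, array weights, the variance trend, 1 probe per gene, other thresholds and leaving out each array. Added after seeing the data were the fit to 16 separate arrays in its place as an alternative, the 16 arrays with the source as a random block, and leaving out each source.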

Results

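Gene expression in samples labelled as dorsal skin of 15-day-old mice was measured on 16 single-colour Illumina bead arrays. The labels assign 7 arrays to mice carrying a K14-cre transgene and a floxed allele of Gab1, and 9 arrays to control mice. K14-cre expresses Cre recombinase from the keratin 14 promoter, which is active in basal keratinocytes. Gab1 is a docking protein that links receptor tyrosine kinases to downstream signalling. The series' design text describes sorted cells positive for integrin alpha 6, whereas the tissue label of each array says dorsal skin, and the text does not settle which was hybridised. Between 13406 and 14636 of the 25697 probes were detected per array (52.2% to 57.0%), and 14504 probes were tested.

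The 16 arrays fell into 5 sets whose members were nearly interchangeable. Arrays of one set correlated at 0.994 to 0.996 (18 pairs), and arrays of different sets at 0.935 to 0.936 in the mutant group (median 0.936) and 0.961 to 0.986 in the control group. Mutant and control arrays correlated at 0.933 to 0.964 (median 0.956), so that the 2 mutant sets were less alike than mutant and control arrays typically were. The median SD of a probe was 0.108 on the log2 scale between arrays of a set and 0.25 between sets of a group. The arrays of a set differed far less than those of different sets, and each set was therefore counted as 1 sample, referred to as a source. The mutant group comprised 2 sources, with 3 and 4 arrays, and the control group 3 sources with 3 arrays each. The labels do not say which arrays share RNA, or whether the sources are separate animals or pools. The limma p-values set a difference against the spread between these sources, moderated across probes, which need not be the spread between animals. At the preset correlation, camera sets the genes of a list against the other genes.

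**Figure D1:**
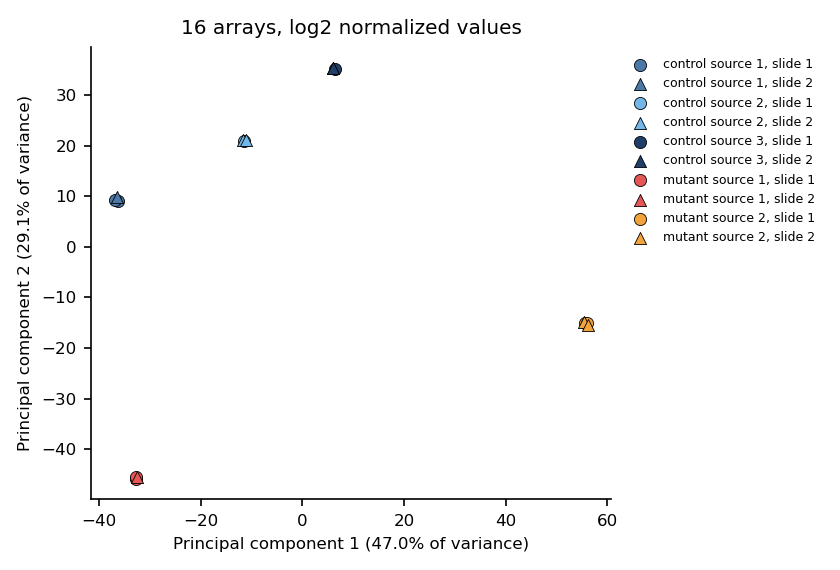
Positions of the 16 arrays on the first 2 principal components of the log2 normalized values (47.0% and 29.1% of the variance). Colours mark the 5 sources, circles slide 1 and triangles slide 2. The arrays of each source lie together on both slides, and mutant source 2 lies alone at one end of the first component.

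Gab1, the gene targeted in the mutant, was examined first. Its signal averaged 11.65 ± 0.44 (SD, n = 2 sources) in the mutant and 12.69 ± 0.01 (SD, n = 3) in the control on the log2 scale, so that the mutant held 48.9% of the control level. Both mutant sources lay below all control sources, and every mutant array (11.27 to 12.01) lay below every control array (12.60 to 12.78). The log2 difference of -1.03 (SE 0.21) had a limma adjusted p of 0.239. The exact two-sided permutation test over the 5 sources gave p = 0.1, the smallest value that 10 splits allow. Gab1 is read by 1 probe, whose position relative to the deleted part of the gene is not given in the sources used here, so the probe need not report the deletion itself.

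The comparison of mutant with control arrays asked which transcripts differ when Gab1 is deleted in K14-positive cells. Transcripts of S100a9, Krt42 and Prss35 were higher in the mutant, and those of Mc5r and Avpr1a were lower. S100a9, a subunit of calprotectin that inflamed keratinocytes and myeloid cells make, rose from 5.80 ± 0.54 (SD, n = 3) to 11.29 ± 0.57 (SD, n = 2), a log2 difference of 5.49 (SE 0.41). Krt42, a type I keratin, rose by 3.98 on the log2 scale (SE 0.24), from 7.89 ± 0.15 to 11.88 ± 0.44. Prss35, which encodes a protein of the serine protease family, rose by 2.76 (SE 0.21).

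Mc5r, the melanocortin receptor of sebaceous glands, fell by 2.95 (SE 0.22), from 8.70 ± 0.26 to 5.75 ± 0.04. Avpr1a, a vasopressin receptor, fell by 2.26 (SE 0.15), and its other probe fell by 2.18. S100a9 was above background on 5 of the 9 control arrays and Mc5r on 3 of the 7 mutant arrays, and without background correction they differed by 3.77 and -1.53. Each of these 5 genes differed in the same direction in both mutant sources, at a limma adjusted p of 0.0470. In all, 8 of the 14504 probes passed (3 higher, 5 lower), of which 2 have no gene symbol here, and 1760 had an unadjusted p below 0.05 where 725 are expected without an effect; other splits of the 5 sources into 2 and 3 gave between 16 and 1966 such probes, so the excess does not single out genotype. Within slide 1 and within slide 2 no probe passed (adjusted p of these genes 0.0515 and 0.0509, with 1634 and 1662 probes at an unadjusted p below 0.05), while the 5 differences moved by at most 0.11.

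**Figure D2:**
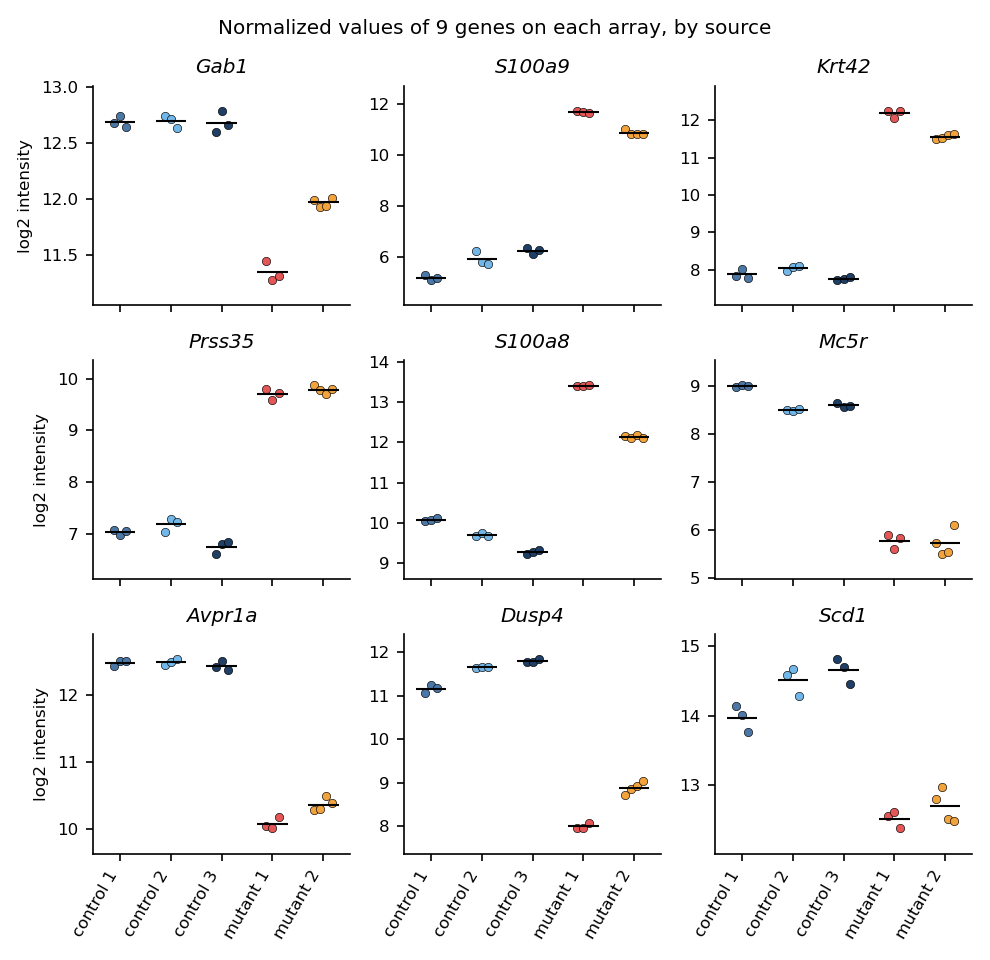
Log2 normalized intensity of 9 genes on each of the 16 arrays (points), grouped by source, with the mean of each source as a bar. Both mutant sources lie apart from all 3 control sources for each gene, with S100a9 at 11.29 on average against 5.80 and Mc5r at 5.75 against 8.70. Of the 9 genes, Gab1, S100a8, Dusp4 and Scd1 did not pass the adjusted threshold, and each panel has its own scale that does not start at 0.

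Treating the 16 arrays as separate samples, the fit set before the data were examined, gave 4914 probes (2525 higher, 2389 lower), all 8 above among them. Over the tested probes, 15.8% were higher and 14.0% lower in both mutant sources than in all control sources. The average over all splits of the 5 sources is 10% in each direction. Probes vary together and the shares of the other splits were not computed, so this excess does not single out genotype. The 8 calls rest on small margins: no probe passed when any 1 of the 5 sources, or control array 2, 4 or 6, was left out. None passed without background correction, with offset 50, with 75th percentile scaling, with the authors' table or with the Y-linked level as a covariate, and 1 passed with cyclic loess, while the 5 named genes kept their direction in each of these.

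The coordinated behaviour of 41 gene lists, for 27 pathways or compartments of the skin and 14 cell types, was then tested with camera. Sebocyte and fatty acid synthesis genes, endothelial, dermal papilla and T cell markers, and hair shaft keratins were among the 10 lists that fell in the mutant, and genes of wounded or inflamed keratinocytes and of cell division were the 2 that rose. None of the 12 held with an estimated correlation between genes (0 of 41 lists, smallest camera adjusted p = 0.577, 1 list at an unadjusted p below 0.05). In that form camera has only the 3 residual degrees of freedom of the sources, which few lists could pass over 41. For CDK inhibitors the estimated correlation was -0.07, yet the unadjusted camera p went from 0.00281 to 0.0549. The losses therefore cannot tell correlation between genes from the small number of sources. Fry, which tests each list by itself, called 0 lists with a direction (smallest adjusted p = 0.119, 9 with an unadjusted p below 0.05) and 7 with changes in either direction. With the Y-linked level as a covariate only the sebocyte and cell division lists of the 12 stayed past the camera threshold. The Y-linked Eif2s3y was 4.78 in mutant source 2 and 9.14 to 10.74 in the other sources. The covariate therefore largely marks mutant source 2 and does not isolate sex. Of the 10 possible splits of the 5 sources into 2 and 3, 6 gave at least as many lists, the real split included. Of the 12 lists 10 had a smaller camera p in another split than between mutant and control, so the small p of a list does not single out genotype. Without mutant source 1 the hair shaft, CDK inhibitor and adipocyte lists no longer passed, nor did cell division, whose median was then -0.05. Without mutant source 2 the hair shaft, wounded keratinocyte, adipocyte, melanocyte and T cell lists no longer passed. All 12 stayed past the camera threshold within each slide, and no median moved by more than 0.09.

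The sebocyte and fatty acid synthesis list fell (median log2 difference -1.33, 15 genes, adjusted p = 2.30e-12; adjusted p = 0.577 with an estimated correlation). Of its 15 measured genes 11 were lower in both mutant sources and none was higher. Mc5r passed over all genes, and 11 genes passed when adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, differed by -1.78 (SE 0.23, adjusted p = 0.188), and Pparg, a regulator of lipid storage genes, by -1.80. Elovl3, above background on 4 of the 7 mutant arrays, and Cidea differed by -2.81 and -2.70, whereas Fasn, above background on 6 of the 7 mutant arrays, and Acaca differed by -0.10 and -0.12 with overlapping sources.

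Cholesterol synthesis genes fell (median -0.49, 15 genes, adjusted p = 0.00123; adjusted p = 0.609 with an estimated correlation), with 9 genes lower and 1, Sc5d, higher in both mutant sources. No gene of this list passed over all genes and 1 passed when adjusted over the list alone. Hmgcs1, which makes the precursor of mevalonate, differed by -0.66 (adjusted p = 0.239) and Idi1, above background on 3 of the 7 mutant arrays, by -0.59 (adjusted p = 0.313). The adipocyte list fell (median -1.03, 4 genes, adjusted p = 0.0184; adjusted p = 0.630 with an estimated correlation). Lpl and Adig differed by -0.99 and -1.67, and the sources overlapped for Adipoq. The median of this list was -0.39 without a filter on dim probes and -0.68 without background correction. No adipocyte gene passed over all genes and 3 passed when adjusted over the list alone.

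Keratinocyte genes of wounded or inflamed skin rose (median 1.16, 19 genes, adjusted p = 1.65e-06; adjusted p = 0.577 with an estimated correlation). Of these 8 were higher and 0 lower in both mutant sources. The median was 1.83 without mutant source 1, 0.92 without mutant source 2 and 0.024 with the Y-linked level as a covariate. S100a9 passed over all genes, and 6 passed when adjusted over the list alone. S100a8, the partner of S100a9 in calprotectin, differed by 3.10 (SE 0.44, adjusted p = 0.198). The hyperproliferation keratins Krt6a, above background on 6 of the 9 control arrays, and Krt6b differed by 1.32 and 1.41, while Krt16 differed by 1.05 with overlapping sources, as did Il6 at -0.63 and Lcn2 at 0.52.

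Of the lists for the hair follicle and its surroundings, those for the dermal papilla, the hair shaft and melanocytes fell and 4 others did not pass. Dermal papilla genes fell (median -1.40, 10 genes, adjusted p = 8.56e-06; adjusted p = 0.577 with an estimated correlation), with 5 lower in both mutant sources, 0 past the threshold over all genes and 2 when adjusted over the list alone, and the median was -0.78 without mutant source 2. Hey1, a Notch target, differed by -1.32 (adjusted p = 0.237) and Igfbp4 by -0.74 (adjusted p = 0.238). Hair shaft keratins and their associated proteins fell (median -1.60, 9 genes, adjusted p = 0.00287; adjusted p = 0.577 with an estimated correlation). Krt33a differed by -2.14 (adjusted p = 0.270) and Krt31, above background on 6 of the 7 mutant arrays, by -1.82 (adjusted p = 0.347), and no gene of the list passed over all genes or when adjusted over the list alone. The median of the hair shaft list was -0.25 without a filter on dim probes, -0.79 without background correction, -0.84 with the authors' table, -1.05 with offset 50 and -0.89 without mutant source 2. Melanocyte genes fell (median -0.83, 7 genes, adjusted p = 0.00391; adjusted p = 0.630 with an estimated correlation), and among them Mlana, a melanosome protein, differed by -2.26 and Oca2, above background on 1 of the 7 mutant arrays, by -0.83. No melanocyte gene passed over all genes and 1 passed when adjusted over the list alone. The melanocyte median was -1.37 with the stricter filter, -1.84 without mutant source 1, -0.17 without mutant source 2 and -1.35 without control source 3. The upper follicle (6 genes, median -0.05, adjusted p = 0.828), the inner root sheath and medulla (13 genes, median 0.02, adjusted p = 0.575), the matrix transcription factors (14 genes, median -0.00, adjusted p = 0.865) and the stem cell genes of the bulge and hair germ (15 genes, median 0.17, adjusted p = 0.572) did not pass. In that list Lgr5 and Fgf1 differed by 0.76 and 0.57, and Cd34 by -0.76.

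Markers of endothelium and T cells were lower as well. The endothelial list fell (median -0.87, 10 genes, adjusted p = 1.19e-05; adjusted p = 0.630 with an estimated correlation), 7 of its genes being lower in both mutant sources. Esam and Pecam1, which encode junction proteins, differed by -1.18 and -1.03. The T cell list fell (median -2.29, 8 genes, adjusted p = 0.000307; adjusted p = 0.630 with an estimated correlation). Nkg7 and Ctsw, genes of cytotoxic lymphocytes, differed by -2.60 and -2.53, and Cd3e by -2.74, with 4, 6 and 3 of the 7 mutant arrays above background. The T cell median was -1.52 without a filter on dim probes, -1.33 without background correction, -1.39 with the authors' table and -1.31 without mutant source 2. No gene of either list passed over all genes, while 0 endothelial and 4 T cell genes passed when adjusted over the list alone. Dermal fibroblast genes (14 genes, median -0.07, adjusted p = 0.575) and mural and smooth muscle genes (7 genes, median 0.12, adjusted p = 0.130) did not pass.

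**Figure D3:**
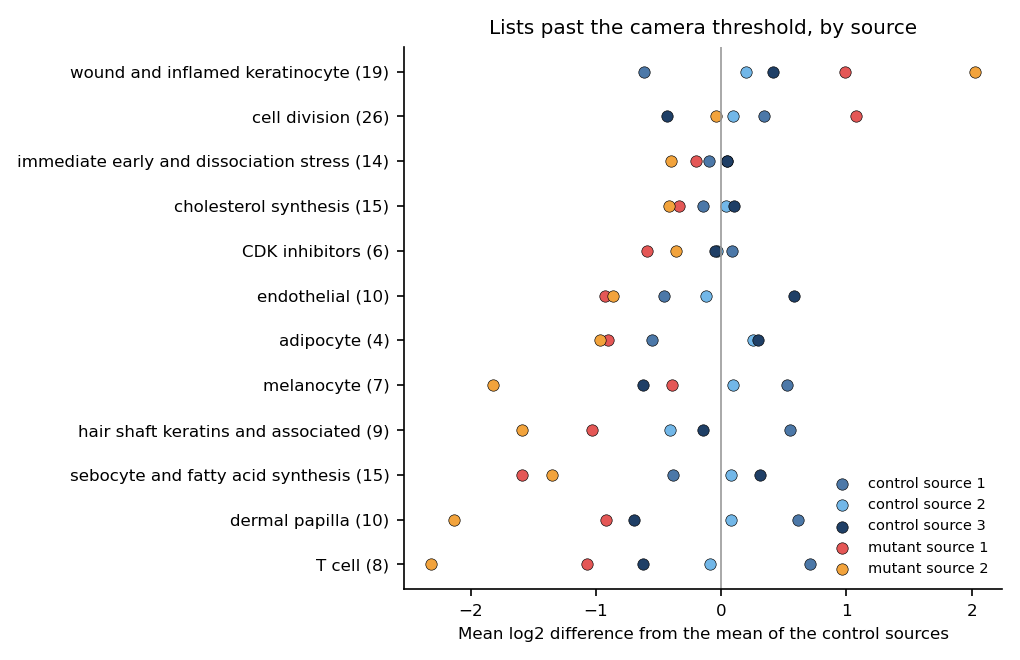
Mean log2 difference of each source from the mean of the control sources for the 12 lists past the camera threshold, with the number of measured genes in brackets. Points are sources. The sebocyte and fatty acid synthesis list stands at -1.59 and -1.35 in the mutant sources and between -0.38 and 0.31 in the control sources, whereas cell division stands at 1.08 in mutant source 1 and -0.04 in mutant source 2.

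Cell division genes rose (median 0.50, 26 genes, adjusted p = 0.000276; adjusted p = 0.773 with an estimated correlation), but the shift lay in mutant source 1, at 1.08, and not in mutant source 2, at -0.04. The median was -0.05 without mutant source 1, 1.11 without mutant source 2 and 0.25 without control source 3. Only Ccne2, Mcm7 and Cdc6 were higher in both mutant sources. For Mcm7 the margin was below the spread between arrays, at 7.58 in mutant source 2 against 7.56 in control source 1 (array SD 0.14). Ccne2, a cyclin of the G1/S transition, differed by 0.96 (adjusted p = 0.301) and the replication helicase subunit Mcm7 by 1.16 (adjusted p = 0.421). Inhibitors of cyclin-dependent kinases fell (median -0.55, 6 genes, adjusted p = 0.0105; adjusted p = 0.577 with an estimated correlation), with 4 lower in both mutant sources. The list did not pass without a filter on dim probes (median -0.53, adjusted p = 0.0654). Cdkn1b, which encodes p27, differed by -0.84 and Cdkn1c by -0.58. No gene of these lists passed over all genes or when adjusted over the list alone.

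Gab1 feeds into the ERK pathway, and the ERK-responsive list gave no shift in one direction (20 genes, median -0.04, camera adjusted p = 0.447). Fry called changes in either direction (fry adjusted p = 0.00100), but it was not run on the other splits of the sources. That call therefore does not single out genotype. Of its genes 6 were lower and 2 higher in both mutant sources, 0 passed over all genes and 1 when adjusted over the list alone. Dusp4, a phosphatase that inactivates ERK, differed by -3.10 (SE 0.34, adjusted p = 0.132), and its other probes by -1.07 and -2.63. Etv1, above background on 1 of the 7 mutant arrays, differed by -0.84 and Spry4 by -0.72, whereas Phlda1 and Lif differed by 0.76 and 0.94. Immediate early genes fell (median -0.30, 14 genes, adjusted p = 0.00391; adjusted p = 0.577 with an estimated correlation), with 8 lower in both mutant sources. Jund differed by -0.87 and Klf2 by -1.31, and no gene of that list passed over all genes or when adjusted over the list alone.

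The BMP and Smad list (16 genes, adjusted p = 0.539) and the catagen-associated list (14 genes, adjusted p = 0.610) did not pass. Id1 and Id2, targets of BMP signalling, differed by -0.88 (adjusted p = 0.314) and -0.64 (adjusted p = 0.350), and the nuclear receptors Vdr and Rxra by 0.47 and -0.66. In the 8 lists whose median, mean and test differed in sign, none passed.

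Transcripts of the sex chromosomes differed between the sources as well. The Y-linked Eif2s3y stood at 9.14 in mutant source 1, 4.78 in mutant source 2 and between 10.41 and 10.74 in the control sources, and was above background on 3 of the 7 mutant arrays. Kdm5d, also Y-linked and above background on 1 of the 7 mutant arrays, differed by -1.74 (adjusted p = 0.207). Xist, expressed from the inactive X chromosome, was 10.43 and 11.49 in the mutant sources and between 9.93 and 10.50 in the control sources. The sex-linked list did not pass (4 genes, adjusted p = 0.130; 1 gene when adjusted over the list alone).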

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

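The 80 combinations of a value and a group were checked for a single array far from the others of its group, and 2 stood out. Independent arrays would give about 4 by chance. The arrays of a group form sources, so that number need not apply, and gaps between sources can hide a far array. Vdr on mutant array 7 was 12.51 on the log2 scale, against 12.76 to 12.86 on the other mutant arrays. The median raw signal of control array 7 was 175.9, against 197.0 to 214.9 on the other control arrays.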

How the results depend on the processing

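The fit to 16 separate arrays was set before the data were examined and became an alternative after they were seen, when the source as a random block and the removal of whole sources were also chosen. The count of 8 probes is fragile because the adjusted p of its calls lies at 0.0470 to 0.0474. It became 0 without background correction, with offset 50, with 75th percentile scaling, with the authors' table, within slide 1, within slide 2, with the Y-linked level as a covariate, with 1 probe per gene and at an adjusted p below 0.01, while limma left 1177 to 4517 probes at an unadjusted p below 0.05 in these settings. It was 1 (higher) with cyclic loess, 4 without a filter, 5 with the stricter filter, 3396 with the replicate block, 4914 with 16 separate arrays and 883 with the source as a random block. Of the 8 probes, 1, 4, 5, 8, 8 and 8 were among the calls of these 6 settings. Leaving out single arrays or sources gave 0 to 8 probes. It gave 0 without control array 2, 4 or 6 and without any 1 source, where a lone mutant source is assumed to vary like the controls; 748 to 3798 probes then had an unadjusted p below 0.05. Gab1 kept its sign in 38 of 38 settings, from -1.70 to -0.72, and passed in 3, at -1.0 with the replicate block, -0.99 with 16 separate arrays and -1.03 with the source as a random block (adjusted p 3.80e-06 to 0.936 over all settings). The number of lists past the threshold went from 12 to 7 with the Y-linked covariate, to 0 with an estimated correlation, to 0 with fry and to 7 with fry's test of either direction, and to between 10 and 15 without single arrays or sources. Of the 7 lists past the threshold with the Y-linked covariate, 2 were among the 12. The direction of the test reversed with it for basal keratinocyte (median -0.42), suprabasal (-2.95), wounded keratinocyte (0.024), p53 (-0.52) and melanocyte (0.66) genes. Among the other lists of the 12, the medians that this covariate moved by over 1.5 times were -0.46 (hair shaft), -0.11 (cholesterol), -0.19 (immediate early), -0.016 (dermal papilla), -0.38 (T cell), -0.89 (CDK inhibitors), -2.08 (sebocyte) and 2.00 (cell division). The mitochondrial list, not among the 12, moved from 0.02 to 0.50 and passed (camera adjusted p = 6.89e-05). Over the settings without single arrays or sources, the medians ran from -0.048 (without mutant source 1) to 1.11 (without mutant source 2) for cell division, from -0.19 (without mutant source 1) to 0.23 (without mutant source 2) for mitochondrial and from -1.02 (without mutant source 2) to 1.43 (without mutant source 1) for suprabasal genes. The cause was not tested. Values with the Y-linked covariate rest largely on mutant source 1, because that level is lowest in mutant source 2. Of the 38 named genes 37 kept their sign in all settings, the exception being Eif2s3y with up to 1.15. Scaling moved the median over all probes between 0.01 and 0.03. The title numbers share only a number, since deviations of same-numbered arrays correlated at -0.39 to 0.42, and that block treats arrays of one source as separate samples. Signal near background limits the differences of S100a9, Mc5r, Etv1, Kdm5d, Oca2, Idi1 and Eif2s3y, which were detected on 5 of 9 control arrays (S100a9), 3 of 7 mutant arrays (Mc5r, Idi1, Eif2s3y) or 1 of 7 (Etv1, Kdm5d, Oca2), and of T cell genes.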

Other observations

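The tests of the sets, the sebocyte list, the cell type lists, the second Zfp330 test and the look at the genes nearest to Gab1 were chosen after the results were seen, and the test of the share among the neighbours of Gab1 and the splits of the sources before.

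The mutant sources differed from each other in several gene groups that the comparison with controls did not call. Suprabasal differentiation genes stood at -1.15 in mutant source 1 and 1.47 in mutant source 2 relative to the control mean (20 genes, camera adjusted p = 0.62 between groups). Macrophage genes stood at 1.05 and -0.69, and Langerhans and dendritic cell genes at 0.87 and -0.48. Matrix transcription factors stood at 0.49 and -0.55. Control sources also spread, with macrophage genes between -1.19 and 0.90 and dermal papilla genes between -0.70 and 0.61. These differences between sources of one group were not tested.

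The calls were set against the other splits of the 5 sources into 2 and 3, of which there are 10, too few for a share under 0.05. The real split gave 8 probes and the highest other split 0, so only the real split gave a count that large. At an unadjusted p below 0.05 the real split gave 1760 probes, mutant source 1 with control source 1 gave 1966 and mutant source 2 with control source 3 gave 1700. The real split gave 12 lists, whereas 6 of the 10 splits, the real one included, gave at least as many and the highest other gave 16. Of these 12 lists 10 had a smaller camera p in another split, among them the endothelial list (1.16e-06 against 1.13e-12) and cell division (3.37e-05 against 7.48e-14). With 16 arrays as separate samples the real split gave 4914 probes. Of the 10 splits 3, the real one included, gave at least as many and the highest other gave 6096, which points to the structure of the sources.

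The 16 arrays formed 5 sets. Repeated arrays of 5 RNA preparations are a candidate explanation, since the first 15 slide positions follow the order of the first 5 throughout. The first 5 positions define that order, so only the later ones bear on it. A slide effect as the cause of the sets is argued against, because all 5 sets hold arrays of both slides. A single animal behind each source is argued against for 4 of them, mutant source 1 and the controls, which had both Eif2s3y (9.14 to 10.74) and Xist (9.93 to 10.50) above background on all of their arrays, whereas mutant source 2 had Xist (11.49) without Eif2s3y (4.78). How many animals stand behind each source, and whether they were litter mates, stays open.

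The sebocyte list and 5 cell type lists fell by camera with the preset correlation. All of these calls end with an estimated correlation (camera adjusted p = 0.577 to 0.630), a test with only 3 residual degrees of freedom that few lists could pass. The pattern itself is open, since neither form of the test settles it with 5 sources. Fewer male animals behind the mutant sources stay open for the sebocyte list. Between the 2 mutant sources its fall did not follow the Y-linked signal. Of its 15 genes 5 were nearer to the control mean in mutant source 1, which has Y-linked signal, than in mutant source 2. But Eif2s3y was also lower in mutant source 1 (9.14) than in the controls (10.41 to 10.74), and 2 sources cannot decide. Its median was -2.08 (camera adjusted p = 0.000104) with the Y-linked level as a covariate, which largely marks mutant source 2. In the main fit the non-epithelial lists did not fall equally. The lower quartile of the fibroblast genes was -0.34, above the medians of the dermal papilla, endothelial, T cell, melanocyte and adipocyte lists (-2.29 to -0.83). Those 5 lists were compared because they fell, so this cannot argue against a lower share of non-epithelial cells. The melanocyte median ran from -1.84 without mutant source 1 to -0.17 without mutant source 2. With the Y-linked covariate the dermal papilla, melanocyte and T cell medians were -0.016, 0.66 and -0.38. Fewer sebocytes, lower levels per cell and the loss of Gab1 itself stay open, the last as a hypothesis. The 2 mutant sources cannot separate genotype from other differences between preparations. Whether whole skin or sorted cells were hybridised is also not settled, which limits how the lists of non-epithelial cells can be read.

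Zfp330, which lies near Gab1 with 2 tested genes between them, was chosen after its values were seen. One of its probes was 6.17 and 7.76 in the mutant sources and between 10.31 and 10.62 in the control sources (log2 difference -3.50, SE 0.47, adjusted p = 0.196), whereas the other differed by 0.32. Strain variants altering expression around the engineered allele stay open: 4 of 71 probes of the 49 neighbouring genes had an unadjusted p below 0.05 (5.63%, percentile 6.88 among 10000 random windows, median 11.9%), a share set in advance to count against them, but a variant that acts on a single gene need not raise that share. Both tested genes next to Gab1 had a lower probe. Hhip, above background on 1 of the 7 mutant arrays, differed by -2.03 (limma unadjusted p = 0.0186, adjusted p = 0.327). A Usp38 probe differed by -0.96 (limma unadjusted p = 0.0260, adjusted p = 0.349). The other Usp38 probe and those of Il15, which lies between Gab1 and Zfp330, Smad1 and Abce1 differed by -0.35 to 0.41 (limma adjusted p = 0.555 to 0.986). A window of 49 genes dilutes an effect limited to the nearest ones, so the low share draws no conclusion about them. A strain variant under the low Zfp330 probe may be the cause, as the 0.32 of the other probe leaves it open, and a change of transcript form would look alike.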
